A study of Caenorhabditis elegans with 4 samples.

How the data were processed

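Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on hermaphrodite Caenorhabditis elegans at the L3 larval stage, grown at 20 °C and crosslinked with 2% formaldehyde. The worms, strain OP43, carried a transgene encoding the nuclear hormone receptor NHR-23 fused to GFP, and the fusion protein was recovered with an anti-GFP antibody. The series labels describe 4 samples, 2 ChIP samples and 2 Input samples, where Input is chromatin set aside from the same lysate before the immunoprecipitation (10% of the supernatant, per the labels' protocols). The labels number the replicates 1 and 2 and do not say whether they came from separate cultures, so any spread between them may be technical. Peak lists were analysed for the 2 ChIP replicates, together with 1 combined list for the series. Input values were not analysed here, so no background measured in the same way stands beside the peak counts.

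The files used here were the authors' peak lists, not read counts or signal tracks. Per the file headers, positions are start and end coordinates on WormBase genome build WS220. Peaks were called with SPP and passed through the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates, per the source field of the deposited lists. The versions and settings of both steps, the read depth and the way in which the replicates were merged into the combined list are not given in the sources used here. Each peak carries a score given by the authors, whose scale is not stated in the deposited lists, and a running peak number starting at 1. The score has a ceiling shared by many peaks in each replicate list and a single value throughout the combined list. Score and peak number ran in nearly opposite order in the replicates (Spearman rho -0.998 in replicate 1 and -0.947 in replicate 2), so a low number was read as a better score. For the combined list the peak number was used for ordering, a choice made after the constant score was seen. Apart from a Pearson correlation of log scores between the replicates, scores were used only to rank or select peaks within a list. No column of per-sample values was left unmatched.

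The comparisons of replicate overlap, recovery of the combined list, score concordance and density on the X chromosome, were fixed before the data were examined, as were their alternatives, apart from those given below as added. Peaks shared at least 1 bp to count as overlapping. Chance overlap was taken from 1000 shuffles of the other list within chromosomes, keeping the number and width of peaks (one-sided test, smallest possible p 0.001). Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, because peaks lie in clusters. The correlation of scores across peaks was tested with 1000 permutations. Densities were compared with exact two-sided binomial tests and exact conditional intervals of the ratio. The WS220 chromosome lengths were not used here, so each chromosome was taken to run from position 1 to the last base of any deposited peak. Permutation tests over complete 1 Mb bins, with 100000 permutations (20000 for the interaction), were added after the data were seen. That for X was set once the peak counts per chromosome were known but before its own outcome was, and those for the other chromosomes and the central parts later; where a group had fewer than 10 bins, all regroupings were enumerated exactly, except in the interaction test. Benjamini-Hochberg adjustment was made over the 6 chromosomes or the 6 bin tests of X and the central parts. Also added after the data were seen were the division of each chromosome into 3 parts of equal length (a central part and the outer parts), the spacing of peaks, the densest 20 kb windows, and the shares of peaks by strength.

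The overlap, density, central-part and spacing calculations were tested on simulated lists with known answers before use. In simulated lists of 6000 peaks, an X to autosome ratio of 1.3 was recovered as 1.34. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were reciprocal 50% overlap, peak centres within 100 bp, the better-scoring 50% of each list, the Pearson correlation of log scores, only peaks found in both replicates and leaving out either replicate. Added after the data were seen were merging of overlapping peaks, nuclear chromosomes alone, peak number in place of score, and a shift of the other list by 10 to 100 kb. Leaving out a replicate meant using the best peaks of the other, as many as in the combined list.

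The rule for named genes was to name genes whose promoter held any of the 10 best combined peaks, the best-bound members of lists of genes chosen for moulting and related functions, and both transgene loci, nhr-23 and unc-119. It could not be applied, because the gene table used here follows another assembly, WBcel235, and coordinates were not converted between builds. For the same reason the planned tests of promoter share, gene lists, receptor half-site motifs, promoter and motif share by peak strength, and transgene loci were not run. Peaks are therefore named by position, and the 10 first peaks of the combined list stand in place of the genes.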

Results

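The series mapped where NHR-23, a nuclear hormone receptor required for moulting in C. elegans, was found along the genome in L3 larvae. Candidate binding sites were recorded as peaks, each a region that the authors' calling listed for the NHR-23::GFP immunoprecipitate. Weak entries of the replicate lists need not all be bound sites. Of the last 1000 peaks of replicate 1, 27.4% overlapped a replicate 2 peak, against 17.1% for shuffled lists. The list from ChIP replicate 1 held 30000 peaks, that from ChIP replicate 2 held 25173, and the combined list held 6178. Peak width was nearly constant in the replicate lists: the commonest width was 384 bp in replicate 1 (97.4% of its peaks), 364 bp in replicate 2 (93.3%) and 380 bp in the combined list (58.3%). With 1 width shared by so many peaks, width was not read as the extent of binding. After overlapping peaks were merged, the lists covered 10.8, 8.46 and 1.92 Mb of the genome. The read depth behind the lists is unknown. All positions are in build WS220.

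The combined list began with 10 sites that ranked near the top of both replicates. Its first peak lay on chromosome II from 10563360 to 10563672 and carried number 2 in each replicate. The second, on chromosome III from 3867350 to 3867726, was number 1 in replicate 1 and number 3 in replicate 2. The third, on chromosome IV from 4749905 to 4750232, was number 5 and number 1 in these lists. The next was on chromosome IV from 654762 to 655078 (numbers 3 and 5), followed by a run of 3 sites on chromosome III. These lay from 7854464 to 7854775 (numbers 4 and 6), from 5678932 to 5679243 (numbers 8 and 4) and from 10758966 to 10759348 (numbers 6 and 7). The eighth site lay on X from 15841025 to 15841400 (numbers 7 and 9) and the ninth on chromosome IV from 13240515 to 13240817 (numbers 10 and 13). The tenth was a wider region of 600 bp on X, from 11093772 to 11094371 (numbers 12 and 14). At these 10 sites the peak centres of the replicates lay 1 to 23 bp apart. Of the first 100 combined peaks, 95 were within the first 200 of both replicate lists, and of the first 1000, 984 were within the first 2000 of both.

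The comparison of the replicates asked how far the same sites were called in each. Strong peaks were shared almost without exception, and the shared portion fell steadily down the lists. Of the first 1000 peaks of replicate 1, 99.2% overlapped a replicate 2 peak, against 27.4% of its last 1000. In replicate 2 the share fell from 99.8% of the first 1000 to 39.5% of peaks 24001 to 25000. Over the whole lists, 16726 of 30000 replicate 1 peaks (55.8%, 95% interval 55.2 to 56.3) overlapped replicate 2, where shuffled lists gave 17.3% on average and 17.95% at most. In the other direction, 16462 of 25173 peaks (65.4%, 64.8 to 66.0) overlapped, with 20.2% on average and 21.3% at most by chance. Both shares had a one-sided permutation p = 0.001, the smallest that 1000 shuffles can give. At an equal length of 25173 peaks the shares were 60.8% and 61.1%. With the best 6178 peaks of each replicate they were 72.5% and 71.3%, against a chance level of 4.58% for each. Stricter definitions of a shared peak gave lower shares that stayed above chance. With reciprocal 50% overlap they were 38.9% and 46.3% (chance 8.44% and 9.96%), and with centres within 100 bp, 33.1% and 39.5% (chance 5.09% and 6.03%).

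Few strong peaks belonged to a single replicate. Among the first 1000 peaks of replicate 1, 8 had no counterpart in replicate 2, and the best of these were on chromosome V from 8500426 to 8500609 (number 359) and on chromosome II from 12944554 to 12944746 (number 385). Among the first 1000 of replicate 2, only 2 had none in replicate 1: a peak on X from 13348458 to 13348631 (number 706) and a peak on chromosome V from 10736829 to 10736987 (number 908). These sites were picked out after their values were seen. The named peaks were all narrower than the commonest width of their own list, which makes an overlap less likely. Of the 8 peaks of replicate 1, 3 overlapped a combined peak, as did 1 of the 2 of replicate 2.

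**Figure D1:**
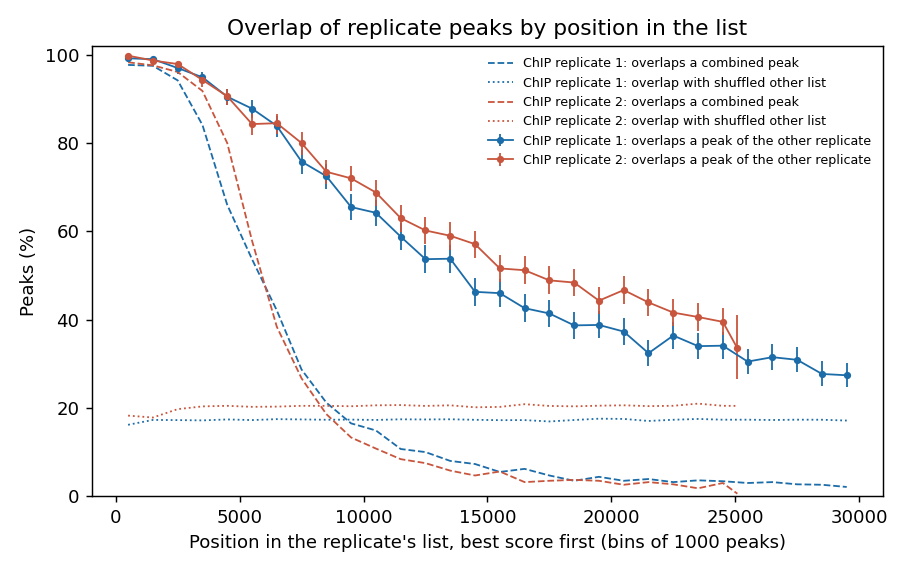
Share of peaks (%, vertical axis) of each ChIP replicate by position in its own list (horizontal axis, bins of 1000 peaks, best score first). Solid lines with exact 95% binomial intervals show overlap with the other replicate, dashed lines overlap with the combined list and dotted lines the mean overlap with the shuffled other list; overlap with the other replicate falls from 99.2% to 27.4% in replicate 1 and from 99.8% in the first bin of replicate 2 to 33.5% in its short last bin of 173 peaks.

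The combined list was compared with the replicates to see which peaks it kept. It was derived from these same replicates, so a high recovery was largely built in. Of its 6178 peaks, 6121 (99.1%, 98.8 to 99.3) overlapped a replicate 1 peak, 6141 (99.4%, 99.2 to 99.6) a replicate 2 peak, and 6084 (98.5%, 98.1 to 98.8) a peak of both. Replicate 1 alone accounted for 37 and replicate 2 alone for 57. The number with a counterpart in neither list was 0 in this full count. It was 753 (12.2%) with reciprocal 50% overlap and 19 (0.308%) with centres within 100 bp. The combined list drew on the top of each replicate: 97.7% of the first 1000 peaks of replicate 1 and 98.3% of those of replicate 2 overlapped a combined peak. Among peaks 5001 to 6000 these shares were 53.7% and 57.9%, and among the last 1000 peaks of replicate 1 the share was 2.1%. The share of combined peaks found in both replicates dropped to 73.6% when reciprocal 50% overlap was required and to 90.2% when centres had to lie within 100 bp.

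The distance between replicate peaks was measured at combined peaks found in both, a selection that itself limits it. Over these 6084 peaks, the centres of the matching replicate peaks lay a median of 30 bp apart (interquartile range 12 to 64 bp), and 86.6% were within 100 bp. The distance grew with peak number. Median distances were 17, 27, 38 and 57 bp from the strongest to the weakest of 4 equal parts of the combined list, and the portion within 100 bp went from 97.3% to 71.7%.

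Peak strength was compared between the replicates across these 6084 peaks, which are not independent replicates. The authors' scores showed almost no relation (Spearman rho -0.0505, permutation p = 0.001). Most of these peaks sat at the score's ceiling: 4324 (71.1%) in replicate 1, 5999 (98.6%) in replicate 2 and 4248 (69.8%) in both. The peak number, which still orders peaks at the ceiling, gave a positive correlation between replicates (rho 0.639, permutation p = 0.001), a comparison added after the ceiling was seen. Part of this correlation is built into the selection of peaks that passed a comparison of ranks between the replicates. Combined and replicate peak numbers correlated with rho 0.832 for replicate 1 and 0.876 for replicate 2.

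Peak density in the combined list was highest on chromosome III (76.7 peaks per Mb), X (69.9) and II (67.96), followed by chromosome I (64.9), and lowest on chromosomes IV (51.2) and V (46.5). Against the rest of the nuclear genome, chromosome III held 1.29 times as many peaks per Mb (exact binomial adjusted p = 3.14e-13) and chromosome V 0.708 times as many (adjusted p = 6.61e-24). By the same exact test the ratio was 0.802 for chromosome IV (adjusted p = 8.67e-10), 1.12 for chromosome II (adjusted p = 9.23e-04) and 1.06 for chromosome I, which did not pass (adjusted p = 0.0842). These tests take peaks as independent. In permutation tests over 1 Mb bins, added after the data were seen, only chromosome V passed (46.8 ± 24.9 peaks, SD, in 20 bins against 65.7 ± 22.7 elsewhere, adjusted p = 0.01). Chromosomes I to IV did not, with permutation adjusted p-values of 0.616, 0.319, 0.0535 and 0.12. The bin tests in turn take neighbouring bins as independent.

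The planned comparison set X, the chromosome subject to dosage compensation in hermaphrodites, against the autosomes. X carried 1239 combined peaks, 20.1% of the nuclear total, at 69.9 per Mb, against 59.9 per Mb on the autosomes. The ratio was 1.17 (95% interval 1.097 to 1.24, exact binomial p = 1.43e-06). Over 1 Mb bins, however, the 17 bins of X (70.0 ± 17.1 peaks, SD) did not separate from the 80 autosomal bins (60.1 ± 25.3), with a permutation p of 0.127 (adjusted p = 0.191). The full replicate lists had no such excess, with X to autosome ratios of 0.951 (0.923 to 0.981) and 1.004 (0.972 to 1.04). The best 6178 peaks of each replicate had ratios of 1.12 (1.05 to 1.198) and 1.17 (1.096 to 1.24).

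**Figure D2:**
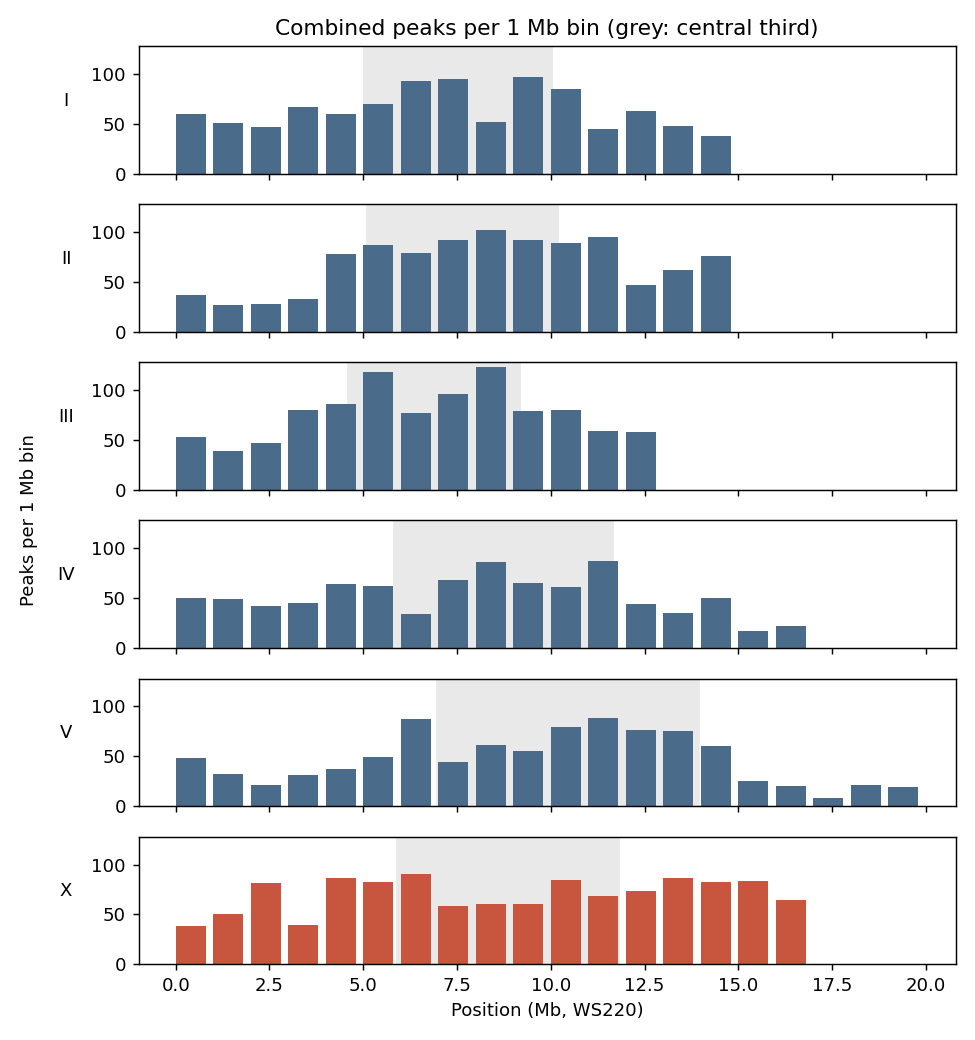
Combined peaks per complete 1 Mb bin (vertical axis) by position in Mb on build WS220 (horizontal axis) for chromosomes I to V (blue) and X (red), with the central part of each chromosome shaded grey. Bins are fuller in the shaded part on the autosomes, with a mean of 79.7 peaks against 50.1 outside it, and alike on X, with 70.3 against 69.8.

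Within the autosomes, peaks were denser near the middle of each chromosome, a comparison made after the bin counts were seen. When each chromosome was divided into 3 parts of equal length, the central part of the autosomes held 78.5 peaks per Mb and the outer parts 50.5, a ratio of 1.55 (1.47 to 1.65, exact binomial p = 5.45e-52). By bins, 79.7 ± 20.8 peaks (SD, 27 bins) in the centre stood against 50.1 ± 21.4 (53 bins) outside (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 6e-05). Each of the 5 autosomes showed this excess, with ratios of 1.43 for chromosome I, 1.55 for II, 1.45 for III, 1.46 for IV and 1.94 for V. On chromosome V the density was 68.6 peaks per Mb in the centre and 35.4 outside. Over each autosome's own bins, exact permutation tests gave adjusted p-values of 0.0207, 0.0252, 0.0207, 0.0207 and 0.0168 for chromosomes I to V. These bin tests treat neighbouring bins as independent, which they are not, so their p-values may be too small. In the full replicate lists the ratio was lower, 1.14 in replicate 1 (over bins, permutation p = 0.0328) and 1.42 in replicate 2 (permutation p = 4e-05).

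X showed no such difference, with 70.6 peaks per Mb in its central part and 69.6 outside (ratio 1.01, 0.900 to 1.14, exact binomial p = 0.81). Its bins held 70.3 ± 14.2 peaks (SD, 6 bins) in the centre and 69.8 ± 19.1 (11 bins) outside (exact permutation p = 0.965). The difference between X and the autosomes in this respect was tested itself: the central excess was smaller on X (interaction of -29.1 peaks per bin, permutation p = 0.0123, adjusted p = 0.0246). In the outer parts X held 1.38 times the autosomal density (1.27 to 1.49; over bins, permutation p = 0.00605, adjusted p = 0.0181). In the central parts the ratio was 0.899 (0.807 to 0.999; over bins, exact permutation p = 0.31, adjusted p = 0.372). In the full replicate lists neither the outer excess nor the interaction passed the threshold over bins. The outer X to autosome ratio was 1.001 (0.964 to 1.04) in replicate 1 and 1.11 (1.07 to 1.16) in replicate 2, with permutation p = 0.843 and 0.318. The interaction had permutation p = 0.232 and 0.0806. Neighbouring bins are not independent, and with X as 1 chromosome against 5 autosomes the smallest exact p that whole chromosomes can give is 0.167.

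**Figure D3:**
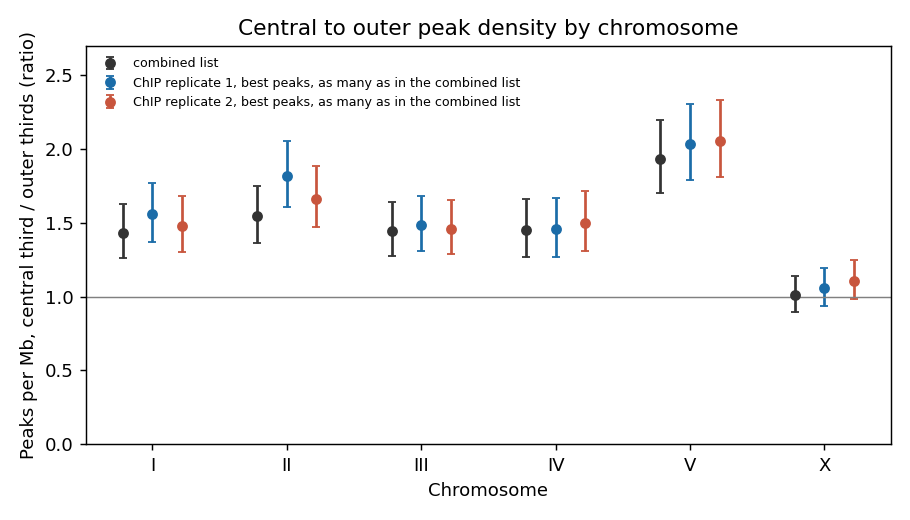
Ratio of peaks per Mb in the central part to peaks per Mb in the outer parts (vertical axis, linear) for each chromosome (horizontal axis), in the combined list and in the best 6178 peaks of each ChIP replicate, with exact 95% intervals; the grey line marks equal density. Chromosome V has the highest combined ratio (1.94) and X the lowest (1.01).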

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

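The coverage of mitochondrial DNA was examined only after its peaks were seen. Both replicate lists held peaks on this molecule, 28 in replicate 1 and 30 in replicate 2, against 0 in the combined list. They drew attention as a signal on a molecule that the density comparisons left out, although the overlap of the replicates included it. Many of these entries repeat a region under another peak number. The 28 of replicate 1 were 18 distinct regions, and the 30 of replicate 2 were 3: a region of 10620 bp listed 23 times, a region of 2684 bp listed 6 times, and a region of 364 bp listed once. The best mitochondrial peak had number 9 in replicate 1 and number 8 in replicate 2, where it was the 2684 bp region. Of the first 1000 peaks of replicate 1, 20 distinct regions had no counterpart in the combined list and 14 of these were mitochondrial. In replicate 2 the corresponding numbers were 5 and 2. Mitochondrial peaks covered 69.3% of the span, taken up to the last base of any peak, in replicate 1 and 98.1% in replicate 2. On the nuclear chromosomes peaks covered 10.7% and 8.42%. No explanation was tested, and Input was not analysed here.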

How the results depend on the processing

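The tests on merged peaks, nuclear chromosomes, a shifted list, peak number, 1 Mb bins, single chromosomes, the central part, spacing, dense windows and shares by strength were chosen only after the files had been read, the bin test of X before its own outcome was known. Of 56 alternatives over 18 results, 38 left direction and side of the threshold, or the value, as reported. Replicate overlap (6 alternatives in each direction), central-part density (5) and close spacing (4) were among them throughout. The share of combined peaks found in replicate 1, replicate 2 and both was 76.5%, 84.9% and 73.6% with reciprocal 50% overlap, 94.1%, 95.8% and 90.2% with centres within 100 bp, and 99.8%, 99.6% and 99.4% in the better-scoring 50%; the stricter definitions lower it by construction. The score correlation was -0.0051 in the better-scoring 50%, where nearly all peaks sit at the ceiling, and 0.639 with peak number in place of score. The X excess lost its call over 1 Mb bins (ratio of medians 1.22), as did the density of chromosomes II (1.13), III (1.29) and IV (0.81). The X share of the strongest minus the weakest of 4 parts ran from 1.61 to 6.29 percentage points, and the central share from -2.73 to 1.198, when either replicate was left out. The chromosome II window that was fullest in the combined list held 11 peaks without replicate 1 and 17 without replicate 2, while the densest 20 kb window of either list held 17. For these the cause was not tested. No paired analysis was possible because Input was not analysed here and peak lists give no model to block. Promoter share, gene lists, motifs, transgene loci and strength by promoter or motif, with their alternatives, were not run for want of a WS220 annotation and genome. Unknown read depth limits what absence from a list means.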

Other observations

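The tests in this part were chosen only after the results were seen, except that those of the combining of the replicates and of a few dense X regions (the bin test of X) were set after the peaks per chromosome but before their own outcomes were known. Combined peaks lay closer together than their number requires. The median distance between neighbouring peak centres was 5781 bp (interquartile range 1791 to 19981 bp), and the longest was 756513 bp. Of 6142 distinct regions, 1331 (21.7%) had a neighbour within 1 kb. Positions redrawn over whole chromosomes gave 11.8% on average and 13.4% at most in 1000 draws, and positions redrawn within 100 kb windows, which keep the regional density, gave 15.2% and at most 17.1% (one-sided permutation p = 0.001 for both, the smallest possible).

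Some 20 kb windows held clusters of peaks. The fullest, on chromosome II from 10542139 to 10562138, held 17 combined peaks and ended just short of the first peak of the combined list. It held 17 of the best 6178 peaks of replicate 1 and 11 of those of replicate 2. Next came a window on X from 6735726 to 6755725 with 16 combined peaks (16 and 17 in the replicates) and a window on chromosome V from 6220969 to 6240968 with 15 (15 and 11). Windows with 13 combined peaks lay on chromosome I from 5870751 to 5890750, chromosome II from 6821239 to 6841238, and chromosome V from 10712031 to 10732030 and from 12534943 to 12554942. The fullest window in any of 200 shuffles held 12 peaks, and the median fullest held 8. The widest region of the combined list, 2669 bp on chromosome III from 7814261 to 7816929, was listed 3 times there under different peak numbers. Nearly the same region was listed 4 times in replicate 1 and 7 times in replicate 2.

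No change of chromosomal share with peak strength passed the test in the combined list. From the strongest to the weakest of 4 equal parts of the combined list, the X share was 20.9%, 20.8%, 19.7% and 18.8%, a difference of 2.06 percentage points between the ends (Fisher's exact test, p = 0.162). In the best peaks of replicate 1 alone the same difference was 6.29 points (exact p = 1.08e-05), and in those of replicate 2 alone 1.61 points (p = 0.28). The central share of autosomal peaks was 44.7%, 43.8%, 43.1% and 43.3%, a difference of 1.34 points (exact p = 0.517). The direction turned in the best peaks of replicate 1 alone, with -2.73 points (exact p = 0.183), and stayed in those of replicate 2 alone, with 1.198 points (exact p = 0.57). All of these Fisher's tests take peaks as independent, although peaks lie in clusters, so their p-values may be too small.

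The higher density of combined peaks on X lay in the outer parts, where the X to autosome ratio was 1.38, against 0.899 in the central parts. It has several possible explanations. A general ease of calling peaks on X was examined in the weaker 50% of the replicate lists. Their ratios were 0.858 and 0.907, with a highest upper bound of 0.951, below the combined list's lower bound of 1.097. The X excess was thus absent among weaker peaks. This cannot decide on ease of calling, because a cause that raised scores on X would move X peaks out of the weaker 50%. Input was not analysed here. In a block bootstrap of means over 1 Mb bins the combined ratio was 1.35 (1.17 to 1.54) and 1.29 (1.17 to 1.41) times that of the weaker peaks. Whether the combining of the replicates made the excess was not settled. The best peaks of single replicates had ratios of 1.12 and 1.17, near the combined ratio of 1.17, with a lowest 95% bound of 1.05. That bound takes peaks as independent, so the combining stays open as a whole or partial cause. Over bins the permutation p was 0.255 and 0.13. This cannot set these lists apart from the combined list, which gave 0.127 itself. A few dense X regions were not told apart from a general excess. The ratio of median bins was 1.22, and the ratio of means without the densest X bin was 1.14, so that bin alone did not make the ratio. The bins' permutation p was 0.127, which asks whether X holds an excess over bins at all. The criterion for excluding such regions, which needed that test to pass, was therefore not met. No biological explanation was tested.

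The central excess on autosomes was not the work of a single chromosome, since all 5 autosomes had a ratio with its interval above 1 and passed the exact tests over their own bins. The intervals take peaks as independent and the tests take bins as independent. The comparison was also made after the bin counts were seen. A regional ease of calling was examined in the same way. In the weaker 50% of the lists the central to outer ratio was 0.884 in replicate 1 and 1.28 in replicate 2. The highest upper bound was 1.33, below the combined list's lower bound of 1.47. In a block bootstrap of means over 1 Mb bins the combined ratio was 1.81 (1.61 to 2.02) and 1.23 (1.12 to 1.35) times that of the weaker peaks. The central excess was thus smaller or absent among weaker peaks. Here too a cause that raised scores in the centre would lower the ratio of the weaker peaks. Ease of calling therefore stays open as a whole or partial cause. The centres of autosomes in this species are richer in genes than the arms, and peaks may follow gene density, a hypothesis that was not tested here for want of an annotation of the same build.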
